A study of Mus musculus with 24 samples.

How the data were processed

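Liver total RNA from male mice, 13 weeks old and fed chow without restriction, was measured at 8 zeitgeber times (ZT0, ZT3, ZT6, ZT9, ZT12, ZT15, ZT18 and ZT21), with 3 arrays at each time and 24 arrays in all. Zeitgeber time counts the hours of the light and dark cycle, with ZT0 at lights on. The labels write the strain as C56bl/6J. Biotinylated single-stranded DNA was made from 300 ng of RNA for a whole-transcript Affymetrix array, which holds several probe sets per gene. Each time point has replicates numbered 1 to 3, and the labels do not say that these are separate animals. The p-values therefore measure the spread between these samples, which may be partly technical.

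The deposited values are on the log2 scale, normalized across arrays by the authors with a method that the labels do not name. The labels list limma, Affymetrix Power Tools 2.10.0 and the mm10 genome build, without saying what each was used for. The array medians lay between 6.44 and 6.51. The highest value, 19.93, was the upper end of the scale. It was reached on at least 1 array by 1283 probe sets, which belong to 314 genes, and changes above it cannot be seen. Only the processed values were used here. Arrays have no read depth, so their number limits the precision.

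The table had 269479 probe sets. Of these, 233753 had 1 gene symbol, 5106 had several and 30620 had none, and only the first kind was used for genes. Old symbols of 2189 genes were updated from the RefSeq table of the same assembly, which also gave the gene positions. A gene's value was the mean of its probe sets, with a median of 8 probe sets per gene. All 23152 genes were tested, with no filter on dim values. As a measure of background, 1101 olfactory receptor genes had a median of 4.40 and a 95th percentile of 6.17 on the log2 scale, and 10289 genes had a mean above that percentile.

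Tests used limma 3.58.1 in R 4.3.3 with empirical Bayes moderation on all 24 arrays, and Benjamini-Hochberg adjustment over all genes with a threshold of 0.05. A time effect was a moderated F over the 8 time-point means. A 24-h rhythm was a moderated F over the cosine and sine terms of a 24-h period. The peak-to-trough range is 2 times the fitted amplitude, and the acrophase is the fitted time of the peak. A 12-h component was a moderated F over 12-h terms added to the 24-h terms. ZT12 minus ZT0 and ZT18 minus ZT6 were two-sided contrasts of time-point means. Errors of time-point means are SDs over 3 arrays, and errors of fitted ranges, acrophases and contrasts are standard errors.

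There were 42 gene lists for the clock, for metabolic and stress pathways and for liver cell types, with 685 genes, of which 627 were measured. For each list with at least 3 measured members, the share of rhythmic members was compared with all other genes by two-sided Fisher's exact test. Of all 23152 genes, 10289 lay above the background percentile. For fatty acid and triglyceride synthesis and for cholesterol synthesis, all 21 and all 20 measured members did. Part of an enrichment may therefore come from expression above background, and this was not told apart. The concentration of the acrophases, the mean resultant length, was compared with 10000 random draws of as many rhythmic genes. Fisher's test and these draws treat the members of a list as independent. The estimated inter-gene correlation was 0.609 for cholesterol synthesis, 0.333 for ribosome biogenesis and 0.277 for heat shock. Where members vary together between arrays, these p-values can be too small. The contrasts of each list were tested with camera, at an inter-gene correlation of 0.01 and again with an estimated correlation. Each family of list tests was adjusted over the lists. The list of mitochondrially encoded genes had no measured member, and the lists of erythroid genes and of cold-inducible RNA-binding proteins had 2 each and were not tested.

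Genes are named by a rule. For the rhythm, these are the genes whose 3 arrays nearest the acrophase all lie above the 3 arrays 12 h away, and of these the 3 with the largest amplitude in each of 8 bins of acrophase. To them are added every measured clock gene, the 3 rhythmic members with the largest amplitude of each other list (or the member with the smallest p where none passed), and the 5 largest rises and falls that passed in each contrast. Unnamed gene models, receptor and immunoglobulin segments and small RNA genes were counted but not named. The time effect, rhythm, 12-h component, both contrasts, the gene lists, the rule for named genes and most alternatives were set before the data were examined. The alternatives were centring each array on its median, quantile normalization, leaving out the dimmest genes, 1 probe set per gene, all probe sets, a trended or robust variance prior, array weights, a replicate block, unmoderated and rank tests, fits on only the 6 arrays of a contrast, and leaving out each array. The median of a gene's probe sets, leaving out probe sets at the highest value, fits without the replicate 1 arrays or without ZT0, and fits on the arrays of 1 replicate number were added after the data were seen. So were the list tests with other scalings or with 1 array left out.

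The tests were tried on simulated data of the same size, with 100 changed genes of each size. The noise was normal and independent between genes and arrays, with 1 spread per gene pooled over the time points. It does not reproduce a wider spread at ZT0 or a shift in phase between replicates, so real recovery may differ. At a peak-to-trough range or difference of 1 on the log2 scale, 81% of rhythmic genes, 56% of the changes at ZT12 minus ZT0 and 62% at ZT18 minus ZT6 were found, and at 2 these were 96%, 92% and 91%. The test for a time effect found 50% and 95% of the same rhythmic genes. Each test called between 4 and 13 unchanged genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.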

Results

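The data are the liver transcriptomes of mice over 1 day, sampled every 3 h at 8 zeitgeber times with 3 arrays each. The series title names a circadian analysis, so the comparisons ask which transcripts follow the time of day, with which size and at which hour. The array medians ranged from 6.44 to 6.51 on the log2 scale. Across genes, the mean correlation of an array with the other 23 arrays was 0.9802 to 0.9855 for 23 arrays and 0.9678 for ZT0 replicate 1.

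The core clock genes had large daily rhythms with ordered peaks. Arntl, also called Bmal1, encodes a transcriptional activator of the clock (chromosome 7, 113178471 to 113314126 in mm10). It had a mean log2 expression of 7.16 ± 1.22 (SD, n = 3) at ZT6 and 12.20 ± 0.14 (n = 3) at ZT21, a fitted range of 5.15 ± 0.50 (SE, 24 arrays) or 35.5-fold, with its acrophase at 19.7 h (adjusted p = 2.39e-06). Nr1d1, which encodes the repressor REV-ERB alpha (chromosome 11, 98767932 to 98775377), went from 11.86 ± 1.04 at ZT3 to 6.37 ± 0.59 at ZT18 (n = 3 each), a range of 35.0-fold with its acrophase at 4.82 h. Dbp, a transcription factor and direct output of the clock (chromosome 7, 45705100 to 45710203), had the largest range of the clock genes, 6.25 ± 0.74 or 76.3-fold, and peaked at 7.58 h (adjusted p = 1.84e-05). Per2, a repressor (chromosome 1, 91415977 to 91459351), rose from 6.83 ± 0.27 at ZT0 to 10.24 ± 0.10 at ZT12 (n = 3 each) and peaked at 12.05 h (adjusted p = 7.34e-07).

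Of the clock activators, 3 of 5 measured members were rhythmic over all genes and 3 adjusted over the list alone, with a mean acrophase of 20.65 h and an adjusted Fisher p of 0.0104. Npas2 had a range of 3.79 ± 0.48 and Clock of 1.63 ± 0.27, and Arntl2 and Rora did not pass (adjusted p = 0.966 and 0.336). Of the clock repressors, 9 of 10 were rhythmic and 10 adjusted over the list alone, with an adjusted Fisher p of 1.23e-08. Their acrophases ran from Nr1d1 through Bhlhe41 at 6.97 h, Nr1d2 at 7.30 h, Ciart at 8.91 h, Per3 at 9.49 h, Cry2 at 10.14 h and Per1 at 10.18 h to Per2 and then Cry1 at 16.92 h. These hours pool the replicates: all 16 rhythmic clock genes peaked later on the arrays of replicate 1 than on those of replicate 2, by a median of 2.3 h, and the order also differs, with Cry2 at 8.04 h before Per3 at 9.09 h on replicate 2. Bhlhe40 did not pass (adjusted p = 0.238). All 4 genes of the PAR bZIP group and their antagonist were rhythmic, with 4 adjusted over the list alone and an adjusted Fisher p of 0.000174. Tef peaked at 8.79 h and Hlf at 10.37 h, and Nfil3, a repressor that binds the same sites as Dbp, peaked at 19.28 h.

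**Figure D1:**
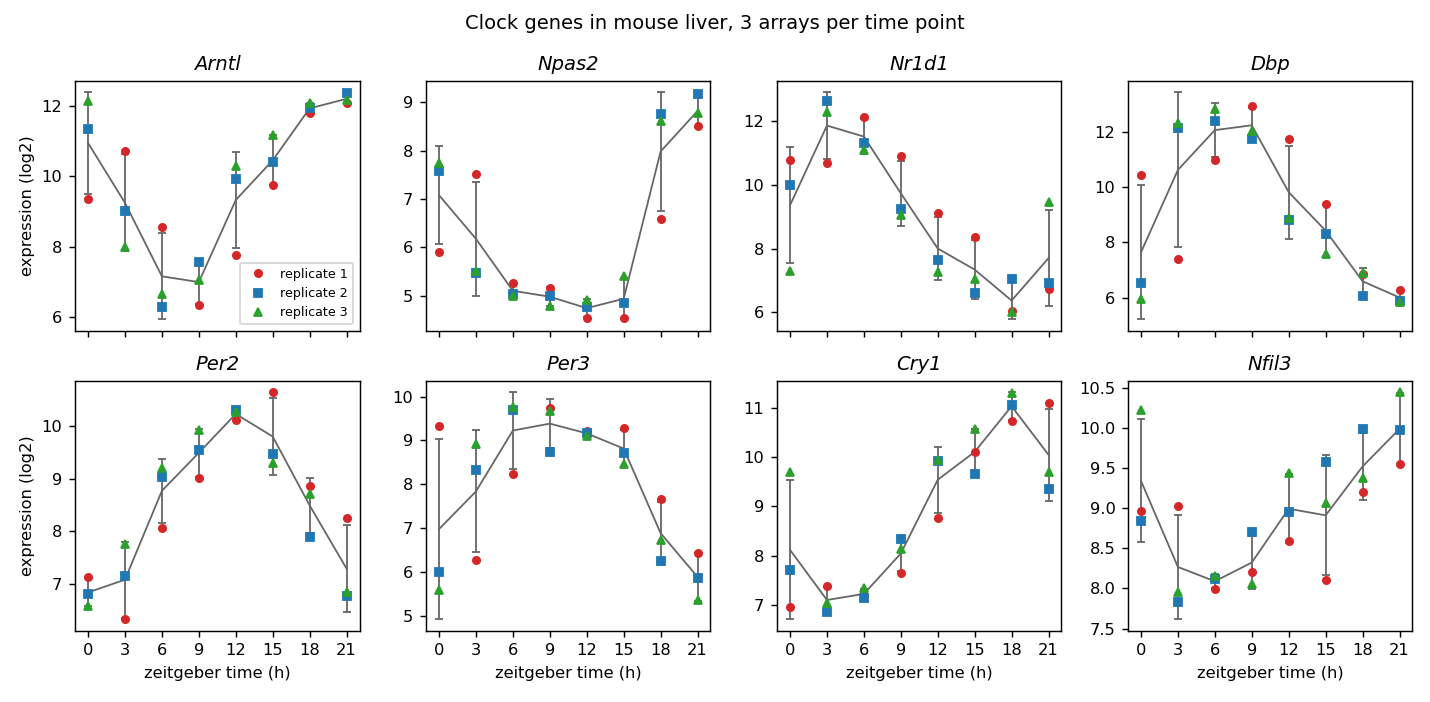
Log2 expression of 8 clock genes against zeitgeber time in hours, with each of the 24 arrays as a point coloured by replicate number, lines through the means and bars of 1 SD (n = 3). Arntl is highest at ZT21 with a mean of 12.20, Per2 at ZT12 with 10.24.

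Among the clock genes, the calls of Cry2 and Hlf rested on few arrays. Cry2 (adjusted p = 0.0252) did not pass without ZT0 replicate 2 (0.0556), ZT0 replicate 3 (0.0506), ZT21 replicate 2 (0.0588) or ZT21 replicate 3 (0.0564), and Hlf (0.0308) did not pass without ZT0 replicate 1 (0.0633), ZT0 replicate 3 (0.0649), ZT9 replicate 1 (0.0616), ZT9 replicate 3 (0.0592), ZT21 replicate 2 (0.0699) or ZT21 replicate 3 (0.061). With the brightest probe set in place of the mean over probe sets, Per3, Ciart and Cry2 did not pass (adjusted p = 0.942, 0.22 and 0.318), and on the 16 arrays of replicates 2 and 3 Cry2 and Hlf did not (0.0626 and 0.134). These 2 also did not pass without the ZT0 arrays (0.0709 and 0.211) or with the median probe set (0.0573 and 0.118), nor Hlf with an unmoderated test (0.0537). The fitted range with the brightest probe set was 0.357 for Per3, 2.00 for Ciart, 1.94 for Arntl, 9.01 for Nr1d1, 4.17 for Tef and 2.19 for Hlf.

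Over all genes, 1592 of 23152 (6.88%) had a 24-h rhythm. Their median peak-to-trough range was 1.77-fold, and 1309 had a range of at least 1.5-fold, 544 of at least 2-fold and 117 of at least 4-fold. Peaks fell at every hour, with 741 genes (46.55%) between ZT0 and ZT12. The most genes peaked nearest ZT21 (283), ZT9 (260) and ZT12 (253), and the fewest nearest ZT3 (114). By clock genes, 7 of the 8 arrays of replicate 1 read earlier than their labels and ZT0 replicate 1 later, by 1.9 h on the curve of replicate 2, with a mean over the 8 of -2.29 h on that curve and -1.62 h on that of replicate 3. Without ZT0 replicate 1, 1567 genes were rhythmic, and on the 16 arrays of replicates 2 and 3 there were 765, of which 692 were among the 1592. With the brightest probe set per gene 760 passed, and the share with peaks between ZT0 and ZT12 was 38.95% on the 16 arrays.

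**Figure D2:**
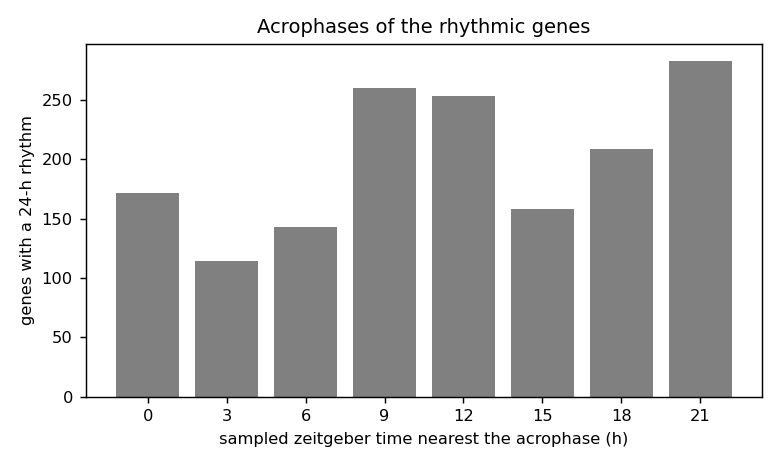
Number of rhythmic genes by acrophase, in bins centred on the 8 sampled zeitgeber times (h). The bins hold between 114 genes (ZT3) and 283 genes (ZT21).

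The genes with the largest ranges at each hour included enzymes and carriers of liver metabolism. Near ZT0 these were Tymp, which encodes thymidine phosphorylase, with a range of 3.08 ± 0.47 (8.46-fold), and Hal, which encodes the histidine-degrading enzyme histidine ammonia-lyase, with 2.02 ± 0.22 (4.05-fold). Near ZT3 they were Abcg8, which encodes a subunit of the biliary sterol exporter, with 2.00 ± 0.38, Slc8b1 with 1.92 ± 0.29 and Casp6 with 1.75 ± 0.26. Gpcpd1, near ZT6, had a range of 3.15 ± 0.54. Near ZT9 were Dbp, Rgs16 (4.36 ± 0.94) and Alas1, which encodes the first enzyme of heme synthesis (3.98 ± 0.47, 15.7-fold). Of the 14 probe sets of Alas1, 5 reached the highest value. Near ZT12 were Lpin1, which encodes a phosphatidate phosphatase of triglyceride synthesis (5.05 ± 0.65, 33.2-fold), Usp2 (4.59 ± 0.57) and Tsku (4.48 ± 0.70). Near ZT15 were Nat8f5 (4.13 ± 0.73), Nat8f6 (3.66 ± 0.50) and Ppp1r3b, which encodes a glycogen-targeting subunit of protein phosphatase 1 (3.58 ± 0.46). Nat8f5 and Nat8f6 belong to a family of similar genes, had 3 and 2 probe sets, and may share signal. Near ZT18 were Chka, which encodes choline kinase (4.63 ± 0.52, 24.8-fold), Cry1 and Pnpla3, and near ZT21 Arntl, Aqp8 (4.29 ± 0.56) and Tubb2a (4.06 ± 0.52). The adjusted p-values of these genes lay between 1.24e-06 (Cry1) and 0.0171 (Pnpla3), and Pnpla3 did not pass on the 16 arrays of replicates 2 and 3 (0.131). With the brightest probe set the range was 1.82 for Gpcpd1 and 5.43 for Pnpla3.

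The lists of fatty acid and triglyceride synthesis and of cholesterol synthesis were enriched in rhythmic genes relative to all other genes, which include those near background. For fatty acid and triglyceride synthesis, 12 of 21 members were rhythmic and 17 adjusted over the list alone, with an adjusted Fisher p of 3.43e-08, a mean acrophase of 15.16 h and an adjusted p of 0.0432 for the concentration of the peaks. After Lpin1, the largest ranges were those of Pnpla3 at 3.36 ± 0.76 with a peak at 17.45 h and of Acacb, which encodes an acetyl-CoA carboxylase, at 2.43 ± 0.52 with a peak at 17.71 h. For cholesterol synthesis, 7 of 20 were rhythmic and 11 adjusted over the list alone, with an adjusted Fisher p of 0.00109, and the peaks were concentrated around 18.73 h (adjusted p = 0.00253). Here and for the lists below, both p-values treat the genes of a list as independent. Pmvk, the phosphomevalonate kinase gene, ranged 7.34-fold with a peak at 18.23 h, Hmgcs1, the HMG-CoA synthase gene, 4.90-fold with a peak at 21.46 h, and Lss, the lanosterol synthase gene, 4.02-fold with a peak at 17.71 h. Hmgcs1 had 1 of its 10 probe sets at the highest value. Acacb did not pass with the brightest probe set (0.106). On the 16 arrays of replicates 2 and 3, 7 synthesis genes of fatty acids and triglycerides and 4 of cholesterol were rhythmic, and Lss did not pass (0.0808). The cholesterol count was also 4 with the brightest probe set (adjusted Fisher p = 0.013).

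Bile acid and fuel genes peaked at different hours. For bile acid synthesis and transport, 7 of 19 were rhythmic and 9 adjusted over the list alone (adjusted Fisher p = 0.000843), with no concentration of the peaks (adjusted p = 0.982). The count was 4 with the brightest probe set (adjusted Fisher p = 0.0117). Cyp7b1, which encodes an oxysterol hydroxylase, had the largest range, 2.18 ± 0.55 with a peak at 9.15 h (adjusted p = 0.0355). It did not pass without ZT0 replicate 3 (0.0561), ZT6 replicates 1 (0.0508), 2 (0.0514) or 3 (0.0556), ZT9 replicates 1 (0.0538) or 3 (0.0783), ZT12 replicates 2 (0.0554) or 3 (0.0547) or ZT18 replicate 1 (0.061), nor with the brightest (0.102) or median (0.0906) probe set, a robust prior (0.0532), an unmoderated test (0.0715) or the 16 arrays (0.0666). Hsd3b7, a bile acid synthesis enzyme gene, ranged 3.82-fold and peaked at 23.15 h. Cyp7a1, which encodes the rate-limiting enzyme of bile acid synthesis, ranged 3.55-fold and peaked at 13.90 h (adjusted p = 0.0341), but did not pass without ZT0 replicate 2 (0.0614), ZT3 replicate 1 (0.0753), ZT3 replicate 2 (0.0578), ZT12 replicate 3 (0.0506), ZT15 replicate 3 (0.0583) or ZT18 replicate 1 (0.05), nor with the brightest probe set (0.0626), an unmoderated test (0.0684) or the 16 arrays of replicates 2 and 3 (0.147).

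For glycolysis and glycogen, 10 of 18 were rhythmic and 13 adjusted over the list alone (adjusted Fisher p = 5.88e-07). Pfkfb3, which makes the glycolytic activator fructose 2,6-bisphosphate, ranged 3.52 on the log2 scale (5.37 with the brightest probe set) with a peak at 9.17 h, and the glycogen-targeting subunit genes Ppp1r3b and Ppp1r3c ranged 3.58 and 3.79 on the log2 scale with peaks at 16.06 h and 20.68 h. For fatty acid oxidation and ketogenesis, 5 of 25 were rhythmic and 12 adjusted over the list alone, without enrichment (adjusted Fisher p = 0.0713). That count was 2 without ZT6 replicate 2, and the enrichment passed without ZT0 replicate 3 (0.0165), ZT12 replicate 2 (0.0103) or ZT18 replicate 1 (0.011), and with each array centred on its median (0.0488). Without any 1 of 11 other arrays the count was 3, as it was on the 16 arrays of replicates 2 and 3 and with the median of the probe sets, and it was 2 with the brightest. Pdk4, which restrains the oxidation of glucose, ranged 12.8-fold with a peak at 20.22 h, and Cpt1a, which encodes the carnitine palmitoyltransferase that admits fatty acids to mitochondria, ranged 2.87-fold with a peak at 7.31 h. Angptl4, which encodes an inhibitor of lipoprotein lipase, ranged 3.14 ± 0.82 with a peak at 8.04 h (adjusted p = 0.0462). It did not pass without any 1 of 15 of the 24 arrays (0.0534 to 0.107), the exceptions being ZT0 replicate 2, ZT3 replicate 1, ZT12 replicates 2 and 3, ZT15 replicates 2 and 3, ZT18 replicates 1 and 2 and ZT21 replicate 1, nor with the brightest (0.0965) or median (0.0768) probe set, a robust prior (0.075), a replicate block (0.0545) or an unmoderated test (0.0892), without the ZT0 arrays (0.0652) or on the 16 arrays (0.0745).

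For gluconeogenesis and fasting, 4 of 13 were rhythmic and 6 adjusted over the list alone. The adjusted Fisher p of 0.0289 did not hold when any 1 of 16 of the 24 arrays was left out (0.0951 to 0.138), the exceptions being ZT6 replicates 1 and 3, ZT12 replicates 2 and 3, ZT15 replicates 2 and 3, ZT18 replicate 2 and ZT21 replicate 1. It was 0.687 with the brightest probe set, 0.657 on the 16 arrays of replicates 2 and 3 and 0.366 without the ZT0 arrays. Slc37a4, the glucose-6-phosphate transporter gene, peaked at 10.30 h with a 2.87-fold range, and Pck1, the phosphoenolpyruvate carboxykinase gene, at 5.94 h with a 5.14-fold range. Of the 11 probe sets of Pck1, 7 reached the highest value, and it did not pass with the brightest probe set (0.309) or on the 16 arrays of replicates 2 and 3 (0.0747).

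Chaperone and ribosome assembly genes peaked around the change from light to dark. For heat shock, 8 of 20 were rhythmic and 11 adjusted over the list alone (adjusted Fisher p = 0.00019), with peaks concentrated around 14.19 h (adjusted p = 0.00253). The chaperone gene Hsph1 ranged 4.78-fold with a peak at 13.24 h and the cochaperone gene Chordc1 2.69-fold with a peak at 13.34 h. Hspa1b, with 2 probe sets, ranged 2.07 ± 0.51 with a peak at 11.94 h (adjusted p = 0.0302). It did not pass without ZT0 replicate 1 (0.0715), ZT3 replicates 2 (0.0522) or 3 (0.053), ZT9 replicate 3 (0.0576), ZT12 replicate 1 (0.0605) or ZT15 replicate 3 (0.0515), nor with an unmoderated test (0.0635), without the ZT0 arrays (0.104) or on the 16 arrays (0.0695), and its range was 3.82 with the brightest probe set. Without ZT3 replicate 3 the list's count was 5 (adjusted Fisher p = 0.0179), as on the 16 arrays of replicates 2 and 3 (0.00194).

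For ribosome biogenesis, 13 of 30 were rhythmic and 22 adjusted over the list alone (adjusted Fisher p = 3.77e-07), with peaks concentrated around 11.11 h (adjusted p = 0.0019). Gnl3, which encodes a nucleolar GTPase, ranged 3.30-fold with a peak at 7.69 h, and Nop2 and Nop56, which act in rRNA modification, ranged 2.69-fold and 2.46-fold with peaks at 11.29 h and 10.38 h. The count was 8 with the brightest or the median probe set and 6 without the ZT0 arrays (adjusted Fisher p = 2.6e-05, 0.000114 and 0.0243). On the 16 arrays of replicates 2 and 3, 4 members were rhythmic (adjusted Fisher p = 0.0532) and neither Nop56 (0.0985) nor Chordc1 (0.0958) passed. Of the 41 measured ribosomal protein genes, 0 were rhythmic with limma and 5 had an unadjusted p under 0.05. The smallest p was that of Rpl14 (adjusted p = 0.0536), which passed without ZT0 replicate 1 (0.0266), ZT0 replicate 3 (0.0482), ZT9 replicate 3 (0.045) or ZT18 replicate 2 (0.0109). It also passed without the dimmest genes (0.0363), with a trended prior (0.0471), array weights (0.0363) or the median probe set (0.0471) and without the ZT0 arrays (0.0233).

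**Figure D3:**
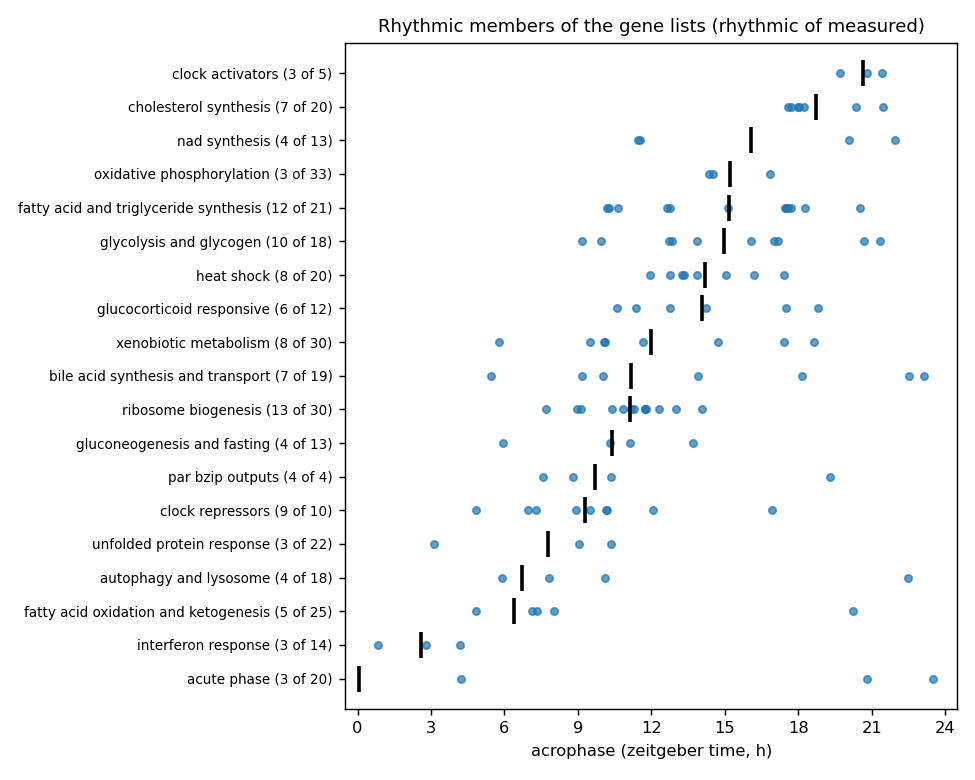
Acrophases (zeitgeber time, h) of the rhythmic members of 19 gene lists, as points, with the circular mean of each list as a bar. The mean lies at 9.28 h for the clock repressors, 11.11 h for ribosome biogenesis, 14.19 h for heat shock and 18.73 h for cholesterol synthesis.

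Markers of several other cell types lay near the background, so that their counts of 0 do not show that a rhythm is absent. The median expression was 4.83 for the neutrophil, 5.13 for the T and NK cell, 5.19 for the B cell, 4.66 for the pancreatic acinar and 5.45 for the adipocyte list, below the 95th percentile of the olfactory receptor genes at 6.17, and 8.01 for the Kupffer cell list. With limma, 0 of 13 Kupffer cell genes, 0 of 11 T and NK cell genes, 0 of 9 B cell genes, 0 of 12 neutrophil genes, 0 of 15 pancreatic acinar genes and 0 of 8 adipocyte genes were rhythmic, and at an unadjusted p under 0.05 these were 0, 0, 1, 0, 0 and 1. Of the endothelial, stellate and biliary markers, 1 of 13, 2 of 12 and 1 of 8 were rhythmic, among them Sox9, a transcription factor gene of biliary cells, with a range of 1.67 ± 0.21 (0.83 with the brightest probe set) and a peak at 20.16 h. Of the erythroid list 2 genes were measured and neither was rhythmic. Of the hepatocyte lists, 1 of 13 identity genes, 2 of 7 periportal genes and 1 of 12 pericentral genes were rhythmic. These were led by the periportal gene Hal and by Slc1a2, a pericentral glutamate transporter gene, which ranged 3.22-fold with a peak at 9.54 h. None of these lists passed Fisher's exact test on all 24 arrays. For the periportal genes it passed without ZT9 replicate 2 (0.0184), ZT15 replicate 2 (0.0313) or ZT18 replicate 1 (0.0177).

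A difference between any of the time points was found for 458 genes, of which 422 also had a 24-h rhythm. Genes with the smallest adjusted p among those named were Per2, Nr1d2 and Pfkfb3 (0.000575 each). Without ZT9 replicate 3 the count was 295, and without ZT18 replicate 3 it was 299. A 12-h component was found by limma for 0 genes, with 1410 at an unadjusted p under 0.05. On the 16 arrays of replicates 2 and 3, chosen after the data were seen, Ciart alone passed, with a 12-h amplitude of 0.79 (adjusted p = 0.000643) against 0.55 (adjusted p = 0.808) on all arrays.

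In ZT12 minus ZT0, 193 genes were higher and 92 lower at ZT12. Lpin1 rose by 4.71 ± 0.88 (SE, n = 3 against 3), from 11.14 ± 1.21 to 15.86 ± 1.03 (adjusted p = 0.012). Usp2, a deubiquitinase gene, rose by 4.07 ± 0.80 and Tsku, a secreted protein gene, by 4.73 ± 0.92 (adjusted p = 0.0141 each). The pseudogene Serpina4-ps1 was 6.54 ± 1.41 higher and Nat8f5 4.63 ± 1.00 higher, and both may take signal from similar genes. Rnf125, a ubiquitin ligase gene, fell by 2.55 (SE 0.52) and the clock activator gene Npas2 fell by 2.34 (SE 0.54). Mki67 and Top2a, genes of dividing cells, had differences of -2.60 ± 0.64 and -2.31 ± 0.52 (adjusted p = 0.05 and 0.0321), and Dmbt1 of -4.77 ± 1.09 (adjusted p = 0.0351). At ZT0, Dmbt1 was 10.93 and 10.64 on replicates 1 and 2 and 4.22 on replicate 3, and Mki67 was 8.54, 6.20 and 10.16 on replicates 1, 2 and 3.

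Camera called 23 of 39 lists in ZT12 minus ZT0, 12 higher and 11 lower. Ribosome biogenesis was higher with 7 of 30 members that rose, 0 that fell and a median of 0.68 (adjusted p = 1.17e-15, and 0.135 with an estimated correlation). Oxidative phosphorylation was higher with 3 of 33 that rose and a median of 0.41 (adjusted p = 1.48e-12, and 0.135 with an estimated correlation). Fatty acid and triglyceride synthesis (2 of 21 rose, median 0.73), glycolysis and glycogen (3 of 18 rose, median 0.24) and heat shock (1 of 20 rose, median 0.55) were higher with adjusted p of 2.04e-05, 0.00014 and 1.74e-05, and of 0.159, 0.135 and 0.196 with an estimated correlation. Clock repressors were higher (2 of 10 rose, median 1.30, adjusted p = 1.48e-06, and 0.135 with an estimated correlation). Male-biased liver genes were higher (1 of 9 rose, median 1.85, adjusted p = 4.54e-06, and 0.135 with an estimated correlation). The sinusoidal endothelial list was higher (0 of 13 passed, median 0.53, adjusted p = 0.00522, and 0.342 with an estimated correlation). The oxidative phosphorylation, male-biased and endothelial lists move with ZT0 replicate 1, on which their median deviations from the other 2 ZT0 arrays were -0.523, -1.245 and -0.702, below all other arrays. Without ZT0 replicate 1 their adjusted p was 1.39e-06, 0.000398 and 0.0344. Male-biased genes were also low on ZT0 replicate 3, the lowest of the other 23 arrays for Cyp2d9, Hsd3b5, Cyp4a12a, Nudt7 and Susd4. There, Selenbp2, Cyp4a12b and Serpina1e lay inside the range of those arrays and Mup20 was at the highest value.

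Lower lists in ZT12 minus ZT0 were led by immune cells. No gene of the Kupffer cell, neutrophil or acute-phase lists passed alone, with medians of -1.46, -1.99 and -0.59 and adjusted p of 6.08e-08, 1.29e-06 and 2.74e-06, or 0.218, 0.252 and 0.198 with an estimated correlation. These lists move with ZT0 replicate 1, on which the acute-phase genes Saa2 and Lcn2 stood at 19.93 and 14.35 and the neutrophil list lay 5.17 above the other ZT0 arrays. Without that array the adjusted p was 0.0216 for the Kupffer cell list, 0.0643 for neutrophils and 0.0112 for acute phase. The interferon list was lower (median -0.49, adjusted p = 0.00014, and 0.184 with an estimated correlation), but not without ZT0 replicate 3 (0.0571). The proliferation list was lower with 3 of 19 that fell (median -0.71, adjusted p = 0.000244, and 0.342 with an estimated correlation), but not without ZT0 replicate 3 (0.135). The immediate-early list was lower (median -0.69, adjusted p = 0.00576, and 0.269 with an estimated correlation). The other 9 calls had adjusted p between 0.0104 and 0.0372, each was lost when at least 1 array was left out, and none held with an estimated correlation, where the lowest adjusted p over both contrasts was 0.0919.

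**Figure D4:**
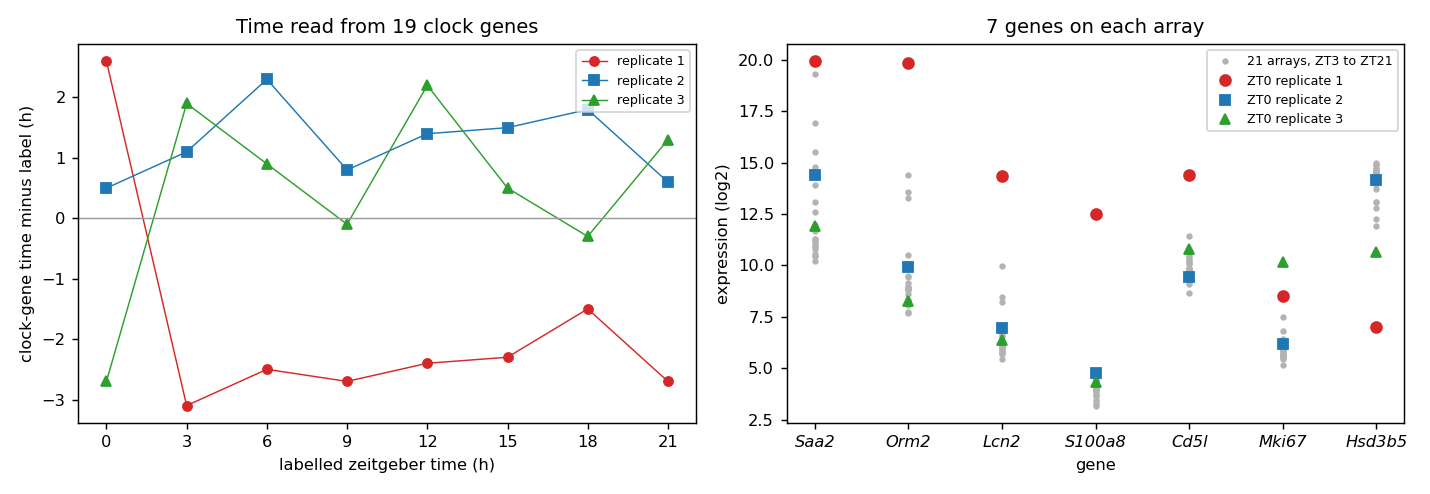
Left, time of day read from 19 clock genes minus the labelled time (h) for each of the 24 arrays, by replicate number. Right, log2 expression of Saa2, Orm2, Lcn2, S100a8, Cd5l, Mki67 and Hsd3b5 on each array, where Saa2 reaches 19.93 and S100a8 12.49 on ZT0 replicate 1.

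The count of 285 genes in ZT12 minus ZT0 depended on single arrays. It was 115 (82 higher, 33 lower) without ZT0 replicate 1, 776 (318 and 458) without ZT0 replicate 2, 39 without ZT12 replicate 1, 95 without ZT12 replicate 2 and 88 without ZT12 replicate 3. The split of 193 higher and 92 lower was 348 and 78 with each array centred on its median and 157 and 121 after quantile normalization. Of the named genes, Lpin1 did not pass without ZT12 replicate 1 (0.0791) and Usp2 not without ZT12 replicate 1 (0.0918) or replicate 2 (0.0501). Tsku did not pass without ZT0 replicate 1 (0.0655), ZT12 replicate 1 (0.0849) or ZT12 replicate 2 (0.0518), and Rnf125 not without ZT0 replicate 3 (0.0534) or ZT12 replicate 1 (0.12). Npas2 did not pass without ZT0 replicate 2 (0.0628) or replicate 3 (0.101), nor without ZT12 replicate 1 (0.136), 2 (0.0959) or 3 (0.0938). Nat8f5 and Serpina4-ps1 did not pass without ZT12 replicate 1 (0.0791 each), 2 (0.0813 each) or 3 (0.0938 and 0.0963), and Serpina4-ps1 also not without ZT0 replicate 1 (0.0519). Dmbt1 and Top2a did not pass without ZT0 replicate 1 (0.164 and 0.0781), ZT12 replicate 1 (0.107 and 0.0791), 2 (0.0959 and 0.108) or 3 (0.104 and 0.0966), Dmbt1 also not without ZT0 replicate 2 (0.0728) and Top2a not without ZT0 replicate 3 (0.0909). Mki67 did not pass without any 1 of 20 of the 24 arrays (0.0531 to 0.159), the exceptions being ZT0 replicate 2, ZT9 replicate 2 and ZT15 replicates 1 and 2. With the brightest probe set per gene, none of the 10 passed (0.0597 to 0.568). On only the 6 arrays of the 2 time points Usp2 passed and the other 9 did not (0.0775 for Tsku to 0.334 for Mki67). On the 16 arrays of replicates 2 and 3, Serpina4-ps1 (0.0903), Nat8f5 (0.0743), Dmbt1 (0.363), Mki67 (0.269) and Top2a (0.232) did not pass, and with the median probe set Dmbt1 (0.121), Mki67 (0.0881), Rnf125 (0.0529) and Top2a (0.0581) did not. A robust prior ended the calls of Dmbt1 (0.058) and Mki67 (0.0631), array weights that of Dmbt1 (0.0684), a replicate block those of Dmbt1 (0.0518) and Mki67 (0.0738) and quantile normalization that of Mki67 (0.0567). Sizes moved too: without ZT0 replicate 1 the difference was 3.90 for Serpina4-ps1 and 2.70 for Nat8f5, and without ZT0 replicate 3 it was -1.67 for Mki67 and -1.52 for Top2a. It was -1.30 for Rnf125 and -1.02 for Top2a with the brightest probe set.

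In ZT18 minus ZT6, 102 genes were higher and 27 lower at ZT18. Arntl rose by 4.77 ± 0.74 (SE, n = 3 against 3), from 7.16 ± 1.22 to 11.93 ± 0.14 (adjusted p = 0.00546), and Cry1 by 3.82 ± 0.51, from 7.22 ± 0.10 to 11.04 ± 0.28 (adjusted p = 0.00426). Chka rose by 4.17 ± 0.76, Aqp8, a water channel gene, by 4.32 ± 0.74 and Pdk4 by 3.94 ± 0.73 (adjusted p = 0.0122, 0.00801 and 0.0136). Nr1d1 fell by 5.14 (SE 0.82), Nr1d2 by 4.04 (SE 0.55) and Dbp by 5.48 (SE 1.12), with adjusted p of 0.00564, 0.00426 and 0.0249. Coq10b, which encodes a coenzyme Q binding protein, fell by 2.21 (SE 0.37) and Ciart, a clock repressor gene, fell by 2.73 (SE 0.59).

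Camera called 8 of 39 lists in ZT18 minus ZT6. Cholesterol synthesis was higher with 1 of 20 that rose and a median of 0.97 (adjusted p = 3.11e-12, and 0.394 with an estimated correlation). The clock activators were higher with 2 of 5 that rose (adjusted p = 0.000164, and 0.0919 with an estimated correlation) and the repressors lower with 3 of 10 that fell and 1 that rose (adjusted p = 1.01e-05, and 0.322 with an estimated correlation). Oxidative phosphorylation and fatty acid and triglyceride synthesis were higher (medians 0.16 and 0.46, adjusted p = 0.000355 each, and 0.553 and 0.409 with an estimated correlation). The latter was not called without ZT18 replicate 1 (0.245). Sinusoidal endothelial and stellate cell markers were higher with 0 members that passed alone (medians 0.59 and 0.63, adjusted p = 1.22e-06 and 0.000201, and 0.394 and 0.502 with an estimated correlation). Immediate-early genes were lower (median -1.03, adjusted p = 0.00114, and 0.409 with an estimated correlation), but not without ZT6 replicate 1 (0.315). The acute-phase list was not called (median -0.30, adjusted p = 0.187), though it was without ZT18 replicate 3 (0.0274) and on the 16 arrays of replicates 2 and 3 (0.0452). At ZT6, Orm2 was 8.96, 13.57 and 14.39 and Saa2 was 11.09, 16.94 and 19.32 on replicates 1, 2 and 3.

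The 129 genes of ZT18 minus ZT6 became 248 without ZT6 replicate 1, 11 without ZT6 replicate 2, 31 without ZT6 replicate 3, 61 without ZT18 replicate 1, 47 without ZT18 replicate 2 and 45 without ZT18 replicate 3. Cry1, Nr1d1 and Nr1d2 passed without each array. Without ZT6 replicate 2, Arntl (0.0511), Aqp8 (0.0825), Chka (0.101), Pdk4 (0.122), Dbp (0.146), Ciart (0.258) and Coq10b (0.0684) did not pass. Chka (0.0839), Pdk4 (0.0749), Dbp (0.136), Ciart (0.197) and Coq10b (0.0608) did not pass without ZT6 replicate 3. Pdk4 (0.0747), Dbp (0.0732) and Ciart (0.0893) did not pass without ZT18 replicate 1, and Chka, Dbp and Ciart not without ZT18 replicate 2 (0.07, 0.111 and 0.117) or replicate 3 (0.0733, 0.0873 and 0.151). With the brightest probe set, Cry1 (0.08), Arntl (0.343), Chka (0.0561), Pdk4 (0.194), Dbp (0.104) and Ciart (0.986) did not pass, and the differences were 1.86 for Arntl, -9.18 for Nr1d1 and -0.159 for Ciart. Dbp and Ciart also did not pass with a robust prior (0.0535 and 0.0504) or the median probe set (0.0714 and 0.0546), nor Ciart with a replicate block (0.065) or on only the 6 arrays (0.0994).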

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

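Tests chosen only after the result was seen are the reading of the ZT0 array of replicate 1, the acute-phase test and the counts of list members on that array. So is the count over the ways to choose 1 array per time point. Predictions were written beforehand for a constant shift, a step at ZT3 to ZT21, a whole-array shift, the hepatocyte share and random assignment. Those on replicate 1 concern patterns found in the same arrays. None was written for Dixon's criterion, the test of 24-h terms by replicate number or the centred reading on the curve of replicate 3.

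Time of day was read from 19 clock genes on curves fitted to other arrays. The arrays of replicate 1 read earlier than their labels at 7 of 8 time points. Their mean offset was -2.29 h (SD 1.72) on the curve of replicate 2 and -1.62 h (SD 1.65) on that of replicate 3. ZT0 replicate 1 stood apart from the 7 others of its number, at 2.6 h late on the curve of the other 23 arrays. At ZT0 it was replicate 3 that read early, at -2.7 h on the curve of the other 23 arrays and -3.7 h on that of replicate 2. The arrays of replicate 2 read 0.5 to 2.3 h late on the curve of the other 23. Single readings can be unstable, since ZT15 replicate 2 read 10.4 h late on the curve of replicate 3. A constant shift of each gene on the replicate 1 arrays is argued against as the whole cause. After each gene was centred within each replicate number, their mean was still -1.99 h (SD 1.65) on the curve of replicate 2. On the curve of replicate 3 it was -1.40 h (SD 1.56), which falls short of the -1.5 h bound set for the curve of replicate 2. A chance order of the 3 arrays within each time point is argued against, since a difference of -2.68 h between replicate 1 and the rest was met or passed in 27 of the ways to choose 1 array per time point (exact p = 0.00412, or 0.0123 after multiplying by 3). A candidate explanation is a step of 1 sampling interval of 3 h between label and tissue for ZT3 to ZT21 of replicate 1. With 751 rhythmic genes outside the clock lists, 7 of these 7 arrays also read 1.8 to 3.5 h early. They are the same arrays that already read early by clock genes, so this reading is not independent. The ZT0 array of replicate 1 read 1.9 h late on the curve of replicate 2. That array also had 309 genes 2-fold above every other array, so its reading cannot exclude such a step for it. A real difference in phase or in the hour of sampling between these samples would give the same reading, was not tested and stays open. No gene passed limma's test for 24-h terms that differ by replicate number. At an unadjusted p under 0.05 there were 1165 of 23152, near the share that this threshold gives without any difference.

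ZT0 replicate 1 stood apart from the 7 other arrays of its number by its mean correlation with the other 23 arrays, 0.9678, and by 309 genes that were 2-fold above every other array. Acute-phase genes on it were high (Orm2 19.83 against a mean of 9.40 on the other 23 arrays, Lcn2 14.35 against 6.54). Of 20 such genes, 15 lay above all other arrays, 4 inside their range and Hamp below it at 14.12 against 18.18. ZT6 replicates 2 and 3 and ZT21 replicate 1 also had Orm2 at 13.57, 14.39 and 13.30 and Lcn2 at 8.23, 9.98 and 8.45. Neutrophil and macrophage genes were high too (S100a8 12.49, Cd5l 14.42 against 9.94). Of the male-biased genes, 6 of 9 lay below all other arrays (Hsd3b5 7.01 against 13.88, Cyp4a12a 6.91 against 12.16). Of the female-biased genes, 3 of 8 lay above them (Cyp17a1 14.89 against 9.63, Sult3a1 9.09 against 4.82, Cyp2b9 8.02 against 5.88). The others of these 2 lists were inside the range. ZT0 replicate 3 was also low for Hsd3b5 (10.64) and Cyp4a12a (10.98), the lowest of the other 23 arrays. It lay below replicate 1 for Susd4 and Nudt7 but inside the range for Selenbp2, Cyp4a12b and Serpina1e. A shift of the whole ZT0 replicate 1 array is argued against, since the neutrophil list lay 5.185 above the other ZT0 arrays after quantile normalization, where no other array exceeded 0.322. RNA from immune cells as the whole cause is argued against by the acute-phase list, made mainly by hepatocytes. Its median deviation was 1.319, where no other array exceeded 0.256. Lcn2, Il1rn, Cd14 and Socs3 of that list are also expressed by immune cells, and 11 of the other 16 lay above all other arrays. A lower share of hepatocytes, which would raise all other cell types, is argued against by the endothelial markers at -0.702 beside the Kupffer cell markers at 3.385. An acute-phase response in that sample stays a hypothesis, found and examined on the same array, and no biological explanation was tested, since the design gives no such group.

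ZT0 replicate 3 had 65 genes 2-fold above every other array, against at most 3 on the 7 other arrays of its number. ZT9 replicate 2 had 19 such genes, against at most 4 on the 7 others of its number. With 9 groups of 8 arrays examined by Dixon's criterion, 5 were outside it, and groups of 3 were not examined. The criterion's chance rate of about 1 in 20 groups holds for normal values and unrelated groups. It does not apply here, since the counts of genes are skewed and ZT0 replicate 1 was outside on each measure.

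A random assignment of the arrays is argued against for the time effect and the rhythm. Of 100 splits of the arrays, 1, the real one, gave as many genes as the 458 with a time effect (highest other 6), and 1 gave as many as the 1592 with a 24-h rhythm (highest other 1). For the 12-h component the real count was 0, so that all 100 splits must give as many and the comparison decides nothing. The highest other had 13. For ZT12 minus ZT0 (285 genes, highest other 1) and ZT18 minus ZT6 (129 genes, highest other 0), 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05.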

How the results depend on the processing

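The fits without replicate 1, without ZT0, on 1 replicate number, with the median of the probe sets and without probe sets at the highest value were chosen after the data were seen. Under median centring, quantile normalization, a trended or a robust variance prior and without probe sets at the highest value, the 5 counts stayed within 1.5 times their values, and a 12-h component was found for 0 genes in every fit except that on 16 arrays. For the results below the cause was not tested. Fits on fewer arrays also have less power, and this was not told apart from other causes. Leaving out the dimmest genes gave 460 genes for ZT12 minus ZT0. The brightest probe set per gene gave 122 genes with a time effect, 760 with a rhythm, 52 for ZT12 minus ZT0 and 29 for ZT18 minus ZT6, and the median of the probe sets gave 222, 907, 116 and 52. Array weights gave 694 genes with a time effect and 396 for ZT18 minus ZT6. All 269479 probe sets, also those without a gene symbol, gave 4591 rhythms, 155 for ZT12 minus ZT0 and 84 for ZT18 minus ZT6. These are counts of probe sets and cannot be set against the counts of 23152 genes directly. An unmoderated test gave 204 genes with a time effect, and ranks gave 971 rhythmic genes. Only the 6 arrays of its 2 time points gave 23 genes for ZT12 minus ZT0. The 16 arrays of replicates 2 and 3 gave 765 rhythmic genes, 1 with a 12-h component, 70 for ZT12 minus ZT0 and 314 for ZT18 minus ZT6. The 8 arrays of 1 number gave 0, 50 and 119 rhythmic genes for replicates 1, 2 and 3. The share of peaks from ZT0 to ZT12 ranged from 38.95% to 50.08% over the settings with all numbers or with 2.

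Leaving out each array in turn gave 295 to 579 genes with a time effect, 1316 to 1730 with a rhythm, 0 with a 12-h component, 39 to 776 for ZT12 minus ZT0 and 11 to 248 for ZT18 minus ZT6. For the rhythms of named genes, 2432 of these results kept their direction and side of the threshold, 81 were lost and 7 gained, and under the other settings 1340 kept, 330 were lost and 5 gained. These other settings include the fits on the 8 arrays of 1 replicate number, which have little power. On replicate 1 alone 0 genes were rhythmic, so every named rhythm was lost there. Pdgfrb, with a range of 0.73 that did not pass without ZT9 replicate 1 (0.0541), ZT9 replicate 3 (0.0506) or ZT21 replicate 2 (0.0513), had its peak on the other side of the day with the brightest probe set (0.174, adjusted p = 0.972) and did not pass with the median (0.263) or on the 16 arrays (0.144), and the fatty acid oxidation list in ZT12 minus ZT0 changed direction on the 16 arrays (adjusted p = 0.387). Camera at an inter-gene correlation of 0.01 called 20 and 10 lists without ZT0 replicate 1 and 21 and 11 on the 16 arrays, against 23 and 8. With an estimated correlation, which was planned, it called 0 of 39 lists in each contrast. The estimates ran from -0.027 for the PAR bZIP list to 0.891 for the neutrophil list.

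The replicate numbers were not treated as pairs. Over all genes, residuals of arrays with the same number had a mean correlation of -0.019 (-0.187 to 0.298), and 4 of 24 arrays correlated best with their own number. By clock genes, however, 7 of the 8 arrays of replicate 1 read early and ZT0 replicate 1 late. A shift in phase leaves residuals that change sign over the day, so these correlations cannot show it. An additive replicate block cannot remove it either. A replicate block gave 322 genes with a time effect, 1435 rhythmic genes, 212 for ZT12 minus ZT0 and 102 for ZT18 minus ZT6. With it the differences of Dmbt1 (adjusted p = 0.0518) and Mki67 (0.0738) in ZT12 minus ZT0 and of Ciart (0.065) in ZT18 minus ZT6 did not pass, nor did the rhythm of Angptl4 (0.0545).

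Signal over background limits the dim genes, since 10289 of 23152 genes lie above the 95th percentile of the olfactory receptor genes, 6.17.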

Other observations

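All tests in this part were planned except the fits on 16 or 21 arrays, the counts of list members on single arrays, the median of the probe sets, the fit without probe sets at the highest value and the list tests with other scalings or with 1 array left out, which were chosen after the results were seen. Cofactor, hormone-response and detoxification genes also had daily rhythms. For NAD synthesis, 4 of 13 measured members were rhythmic and 7 adjusted over the list alone (adjusted Fisher p = 0.0289). Nampt, the rate-limiting enzyme gene of NAD salvage, ranged 6.61-fold with a peak at 11.52 h and Nmrk1, a nicotinamide riboside kinase gene, 3.92-fold with a peak at 11.44 h, while Kynu, of tryptophan breakdown, ranged 2.80-fold with a peak at 21.96 h. For glucocorticoid-responsive genes, 6 of 12 were rhythmic and 7 adjusted over the list alone (adjusted Fisher p = 0.000376). Fkbp5, a cochaperone of the glucocorticoid receptor, ranged 5.61-fold with a peak at 11.39 h, Ddit4 5.55-fold with a peak at 17.51 h and Cdkn1a, a cell cycle inhibitor gene, 5.36-fold with a peak at 18.80 h. With the brightest probe set the range was 4.19 on the log2 scale for Fkbp5 and 4.28 for Cdkn1a, against 2.49 and 2.42. For xenobiotic metabolism, 8 of 30 were rhythmic and 9 adjusted over the list alone (adjusted Fisher p = 0.00285). They included Alas1 and Por, the electron donor gene of cytochrome P450 enzymes, which ranged 5.75-fold with a peak at 10.06 h, the count was 5 on the 16 arrays of replicates 2 and 3 (adjusted Fisher p = 0.0121), and Cyp2a5, with a 3.77-fold range, did not pass on the 16 arrays of replicates 2 and 3 (0.0946) or with the median of its probe sets (0.143), and ranged 4.05 on the log2 scale with the brightest, against 1.91.

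Other lists had no enrichment of rhythmic genes on all 24 arrays. For autophagy and lysosome, 4 of 18 were rhythmic and 7 adjusted over the list alone (adjusted Fisher p = 0.0814). Bnip3, a mitophagy gene, peaked at 10.10 h with a 2.97-fold range and Ulk1, a kinase gene that starts autophagy, at 5.90 h with a 2.76-fold range. The enrichment passed after quantile normalization (7 genes, 0.0012), with the median of the probe sets (0.0138), without the ZT0 arrays (0.0133) and without ZT0 replicate 1 (0.00377), ZT0 replicate 3 (0.0165), ZT3 replicate 3 (0.0126), ZT6 replicate 1 (0.0175), ZT9 replicate 1 (0.0143), ZT15 replicate 2 (0.0283) or ZT18 replicate 2 (0.0151). Of the urea cycle, 2 of 7 were rhythmic and 3 adjusted over the list alone, Asl with a peak at 13.83 h (2.12-fold) and Slc25a15, the mitochondrial ornithine carrier gene, at 22.64 h (1.67-fold), though Slc25a15 did not pass with the brightest probe set (0.0599). The enrichment of this list passed after quantile normalization (0.0379), with the median of the probe sets (0.00606), without the ZT0 arrays (0.02) and without ZT0 replicate 1 (0.0254), ZT3 replicate 3 (0.0179), ZT6 replicate 1 (0.0225), ZT12 replicate 2 (0.0167) or ZT15 replicate 2 (0.0313). The counts were 3 of 22 for the unfolded protein response, 3 of 14 for interferon response (with Ifit1 at a 2.14-fold range, and an adjusted Fisher p of 0.0385 with the median of the probe sets), 3 of 20 for acute phase, 3 of 33 for oxidative phosphorylation, 1 of 31 for the proteasome, 1 of 15 for antioxidant genes, 1 of 19 for proliferation and, with limma, 0 of 13 for immediate-early genes, 0 of 9 for male-biased and 0 of 8 for female-biased genes. In the last 3 of these, 2, 1 and 0 genes had an unadjusted p under 0.05. Of the proliferation and female-biased genes, 7 and 3 lay above the background percentile of 6.17, so that the counts for these lists do not show that a rhythm is absent. Of the cold-inducible RNA-binding proteins, Cirbp was rhythmic with a peak at 2.49 h (1.66-fold, adjusted p = 0.0117), though not with the brightest (0.635) or median (0.216) probe set or on the 16 arrays (0.0738).

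Further rhythms were those of Gpt2 (range 0.88), Herpud1 (1.78), Atf6 (0.79), Trib3 (0.78), Psmd11 (0.67), Ctsl (1.08), Ndufa5 (0.64), Ndufa9 (0.57), Uqcrc1 (0.56), Sod2 (0.52), Socs3 (1.52), Usp18 (1.37), Rsad2 (0.92), Rrm2 (1.11), Hnf4a (0.68), Pigr (0.64), Gpr182 (0.71) and Ecm1 (0.90), with adjusted p from 0.00584 (Pigr) to 0.0381 (Rsad2). Only Ndufa5 and Gpr182 of these passed with the brightest probe set (0.0547 for Psmd11 to 0.999 for Pigr in the others), and only Herpud1, Trib3, Psmd11 and Rsad2 on the 16 arrays of replicates 2 and 3 (0.0553 for Hnf4a to 0.28 for Ecm1 in the others). Trib3, Ndufa9, Uqcrc1, Sod2, Socs3, Rrm2, Hnf4a, Pigr, Gpr182 and Ecm1 did not pass with the median probe set (0.0608 to 0.405), nor Gpt2, Herpud1, Ndufa5, Uqcrc1, Sod2 and Hnf4a without the ZT0 arrays (0.0523 to 0.131). Quantile normalization ended the calls of Ndufa5 (0.0566) and Gpr182 (0.0552), and an unmoderated test those of Socs3 (0.0546), Rsad2 (0.0647) and Ecm1 (0.0614). The range with the brightest probe set was 0.221 for Trib3, 3.22 for Socs3, 0.02 for Pigr, 1.40 for Ndufa5 and 1.64 for Gpr182. Fga (0.71) and Fgg (0.42), with 5 of 8 and 10 of 13 probe sets at the highest value, ranged 1.84 and 1.08 without these probe sets and did not pass with the median probe set (0.62 and 0.629) or with the brightest, nor Fgg on the 16 arrays (0.112) or without the ZT0 arrays (0.0558). Trib3 did not pass without ZT3 replicate 2 (0.0533) or 3 (0.0528), Gpr182 not without ZT15 replicate 1 (0.0665) or 2 (0.0569), and Socs3 not without ZT3 replicate 2 (0.0635), ZT15 replicate 3 (0.0549) or ZT18 replicate 1 (0.055). Hnf4a did not pass without ZT9 replicate 2 (0.0609) or 3 (0.0745), ZT12 replicate 1 (0.0549) or ZT21 replicate 2 (0.0515) or 3 (0.0503). Ecm1 did not pass without ZT3 replicate 3 (0.0616), ZT6 replicate 1 (0.071) or 3 (0.0654), ZT15 replicate 1 (0.0632) or 2 (0.0593), ZT18 replicate 1 (0.0754), 2 (0.0509) or 3 (0.0593) or ZT21 replicate 2 (0.0513). Rsad2 did not pass without ZT0 replicate 2 (0.0544) or 3 (0.0847), ZT3 replicate 1 (0.073) or 3 (0.0615), ZT9 replicate 3 (0.0606), ZT12 replicate 1 (0.0962), 2 (0.0638) or 3 (0.056), ZT15 replicate 1 (0.0629) or ZT21 replicate 2 (0.054) or 3 (0.0532).

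In 10 of the 12 lists with no rhythmic gene, the smallest p was that of Klf6 (adjusted p = 0.153), Cyp4a12a (0.195), Hao2 (0.38), Lyz2 (0.314), Klrb1c (0.274), Ighm (0.0849), Ltf (0.311), Slc4a1 (0.714), Prss2 (0.304) and Lep (0.147). Klf6 passed without ZT15 replicate 2 (0.0432), Cyp4a12a without ZT0 replicate 1 (0.0499) and Ighm without ZT9 replicate 2 (0.0332). Rhythmic genes with the brightest probe set numbered 1 for the unfolded protein response, 2 for autophagy, 1 for oxidative phosphorylation, 1 for interferon and 0 for acute phase.

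On ZT0 replicate 3, 10 of 19 proliferation genes lay above all other 23 arrays, and none of the 9 that act in DNA replication did, although 6 of these 9 lay above both other ZT0 arrays (Rrm2 7.30 against 5.56 and 6.05 on replicates 1 and 2), while Mcm4 lay below both (7.06 against 7.48 and 7.20). Top2a was 8.92 against 7.31 and 5.78 on replicates 1 and 2, Ccnb2 8.23 against 6.12 and 5.91 and Plk1 8.16 against 5.70 and 5.66, genes chosen after their values were seen. That array read 2.7 h earlier than its label by clock genes, a value of -2.7 h on the curve of the other 23 arrays.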
